A study of Bos taurus with 6 samples.

How the data were processed

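Day-7 bovine blastocysts were profiled on the Affymetrix GeneChip Bovine Genome Array, 1 labelled sample per array, in 6 arrays. The 3 superovulated arrays hold blastocysts that grew to day 7 in the reproductive tract of superovulated heifers. The 3 synchronized arrays hold blastocysts whose donors were superovulated as well, but which were flushed at the 2-cell stage on day 2, moved by endoscope into recipients that had only been synchronized, and collected on day 7. Per the labels' protocols, total RNA was isolated with a column kit made for very small samples and biotin was incorporated in the second in vitro transcription, so the RNA was amplified before hybridization. How many blastocysts went into each array is not given in the sources used here. Nothing in the labels says that the 3 arrays of a group came from separate animals or collections. The p-values therefore measure only the spread between these arrays, which may be technical.

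The values deposited by the authors are log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with GCRMA, which by default subtracts a sequence-dependent background, normalizes between arrays and summarizes the probes of a set; its version is not stated. Whether the 6 arrays were normalized together is not given in the sources used here, and the arrays differ more in their number of probe sets above log2 4, 973 to 1894, than quantile normalization over all of them would usually leave. After a second quantile normalization 28 probe sets passed in place of 172. The deposited values ran from 1.45 to 15.97. Detection calls and scanner intensities were not analysed here. GCRMA compresses values near background, so the size of a difference between a bright group and a group near background is uncertain. Each array's values were used as deposited, with no further scaling in the principal analysis.

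The table held 24128 probe sets. The 112 Affymetrix control probe sets were set aside and read only as controls, which left 24016 probe sets for testing. Gene symbols came from the platform's annotation as held by GEO: 13292 of the tested probe sets had 1 symbol, 86 had several and 10638 had none. The symbols covered 9155 genes. Looking them up by gene identifier in the ARS-UCD2.0 gene table matched 13263 probe sets and changed 0 symbols; no coordinates were taken from it. A probe set without a symbol is unnamed here. Genes were not named from probe sets with several symbols.

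The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, no intensity trend), as superovulated minus synchronized, in a two-sided test. P-values were adjusted by the Benjamini-Hochberg method over all 24016 probe sets. A call needed an adjusted p below 0.05. A looser call needed an adjusted p below 0.3 and a difference of at least 2-fold. Intervals given with log2 differences are 95% intervals from the same fit. The genes named by size of change were those with 1 symbol, a call and no overlap between the arrays of the groups: up to 12 rises and 12 falls, with the falls filled up to 8 from the looser calls because few passed. The lineage genes POU5F1, NANOG, SOX2, CDX2, GATA3, KRT8, KRT18 and IFNT and the oviductal gene OVGP1 were to be given in any case where a probe set carried their symbol.

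A set of 28 gene lists was fixed before the data were examined, together with the tests, the naming rule and most of the other settings. The lists covered respiratory chain and ATP synthase, glycolysis, the tricarboxylic acid cycle, cholesterol and fatty acid synthesis, fatty acid oxidation, antioxidant defence, heat shock and the unfolded protein response, apoptosis, cytosolic and mitochondrial ribosomal proteins, translation factors, proteasome, splicing, cell cycle, inner cell mass, trophectoderm, primitive endoderm, blastocyst junctions and transport, maternal oocyte transcripts, interferon response, chromatin regulators, imprinted genes, growth factor signalling, steroid signalling, and markers of oviduct and uterus, of cumulus and granulosa cells and of blood. The Y-linked list had fewer than 5 measured members and was not tested, which left 27. Each gene was represented by its probe set with the highest mean. Lists were tested with camera at its preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, which asks only whether a list's genes move on balance one way. Up to 4 members with the smallest p are named per list, and members named outside that rule are said to have been chosen after their values were seen.

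The array number limits the precision: 3 arrays per group. The procedure was tested on simulated data with the spread of these 6 arrays, in 10 runs over 24016 probe sets. Each run had 200 changed probe sets over both sizes together, drawn only from those with a mean above log2 4. The procedure recovered 8.2% of changes of 1 log2 unit and 25.7% of changes of 2 log2 units. False calls averaged 2.2 per run. These recovery rates apply to such bright probe sets only, and recovery among dimmer ones was not tested. A shifted gene list was found in 50 of 50 runs and an unshifted list was called in 3 of 50. The simulated genes varied independently, so these list rates do not hold for lists whose genes vary together. Since most simulated changes were missed, a gene without a call may still differ.

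Other settings, fixed in the same way, were quantile normalization applied again, median centring, testing only probe sets with a mean above log2 4 or a mean above the median of all, the replicate number as a block, array weights, an intensity trend with a robust prior, an ordinary equal-variance test per probe set, 1 probe set per gene, leaving out each array in turn, the estimated correlation, fry and averaging a gene's probe sets. A further 4 settings were chosen after seeing the data: centring each array on its bright probe sets, centring on the hybridization controls, synchronized array 2 alone against the superovulated arrays, and leaving out superovulated array 3 and synchronized array 2. Control probe sets were compared between groups with exact permutation tests, two-sided, for which 3 arrays against 3 cannot give a p below 0.1.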

Results

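Blastocysts that had developed in superovulated heifers were compared with blastocysts that had been moved on day 2 into recipients without ovarian stimulation. The question was how the reproductive tract of a superovulated animal alters the transcripts of the embryo. Each group held 3 arrays. The groups also differed in handling, since only the synchronized embryos were flushed at the 2-cell stage and transferred. Signals are log2 values, differences are superovulated minus synchronized on the log2 scale, and group values are mean ± SD with n = 3.

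Most probe sets lay near background on every array, with array medians between 2.75 and 2.8. The number of probe sets above log2 4 was 1457, 1578 and 1894 on superovulated arrays 1 to 3 and 973, 1850 and 1184 on synchronized arrays 1 to 3. Across all probe sets, the superovulated arrays correlated with one another at r between 0.928 and 0.974, the synchronized arrays at 0.752 to 0.899, and arrays of different groups at 0.758 to 0.892. These correlations are across probe sets, which are not independent replicates. The ranges within the synchronized group and between the groups thus overlapped. The bacterial hybridization controls, spiked in before hybridization, averaged 10.85 ± 0.03 on the superovulated arrays and 11.66 ± 0.50 on the synchronized ones (exact permutation test, two-sided, p = 0.1, the smallest possible).

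Far more genes were higher than lower in blastocysts from superovulated heifers, with 124 genes up and 2 down. The largest rises were in IFT122, a component of intraflagellar transport, from 3.62 ± 0.97 to 8.44 ± 0.15, and ZBTB18, a transcriptional repressor, from 4.17 ± 0.61 to 8.55 ± 0.19. HSPA14, a ribosome-associated chaperone of the heat shock 70 family, rose by 4.06, and KRT18, a keratin of the trophectoderm epithelium, rose by 3.89. CLGN, a chaperone of the endoplasmic reticulum best known from the testis, was the largest fall, from 9.82 ± 0.60 in the synchronized group to 2.96 ± 0.36 in the superovulated group.

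The other rises named by size were those of CPSF3 (3.61), the endonuclease of mRNA 3' end cleavage, the histone acetyltransferase gene NAA40 (3.47), AGPAT5 (3.39), an enzyme of phosphatidic acid synthesis, the ubiquitin ligase gene MKRN1 (3.34), HSPE1 (3.28), the cochaperonin of the mitochondrial matrix, TMEM184B (3.11), the zinc transporter gene SLC30A5 (3.04) and the lysosomal gene PSAP (2.91). Adjusted p by limma lay between 0.0178 for CPSF3 and 0.0444 for TMEM184B over these 12 rises. In 6 of them the synchronized mean was below log2 4, so the signal there was near background and the size of the rise is uncertain. The other probe set of IFT122 passed too, with a difference of 1.28. For HSPA14, AGPAT5, TMEM184B and PSAP other probe sets of the gene did not pass, with differences between -0.22 for a PSAP probe set and 0.60 for one of AGPAT5.

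Only CLGN (-6.86, adjusted p = 0.0125) and PNRC2 (-2.78, adjusted p = 0.0483), a nuclear receptor coactivator that also acts in mRNA decay, fell among genes with a symbol. CLGN fell on both of its probe sets, the second by 3.35, whereas the second probe set of PNRC2 differed by -0.02. Past the looser threshold only, the zinc finger gene ZC3H18 (-1.21), CCDC93 (-1.17), the calcineurin subunit gene PPP3CC (-1.61), NHLRC2 (-3.09) and CNPY2 (-1.46) were lower in the superovulated group, with adjusted p between 0.0622 and 0.132. The other probe sets of PPP3CC and NHLRC2 differed by no more than -0.24. LOC100174924 was also lower at that threshold (-3.45, adjusted p = 0.0694), but its other probe set differed by 2.06 in the opposite direction. Of the 14 genes named above with a call, 12 were rises and 2 falls. Without superovulated arrays 1, 2 and 3 in turn, 2, 1 and 2 of the 14 still passed. Without synchronized arrays 1, 2 and 3 in turn, 4, 6 and 7 did. All 14 kept their direction each time, which the naming rule fixed beforehand, since it asked for groups without overlap.

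**Figure D1:**
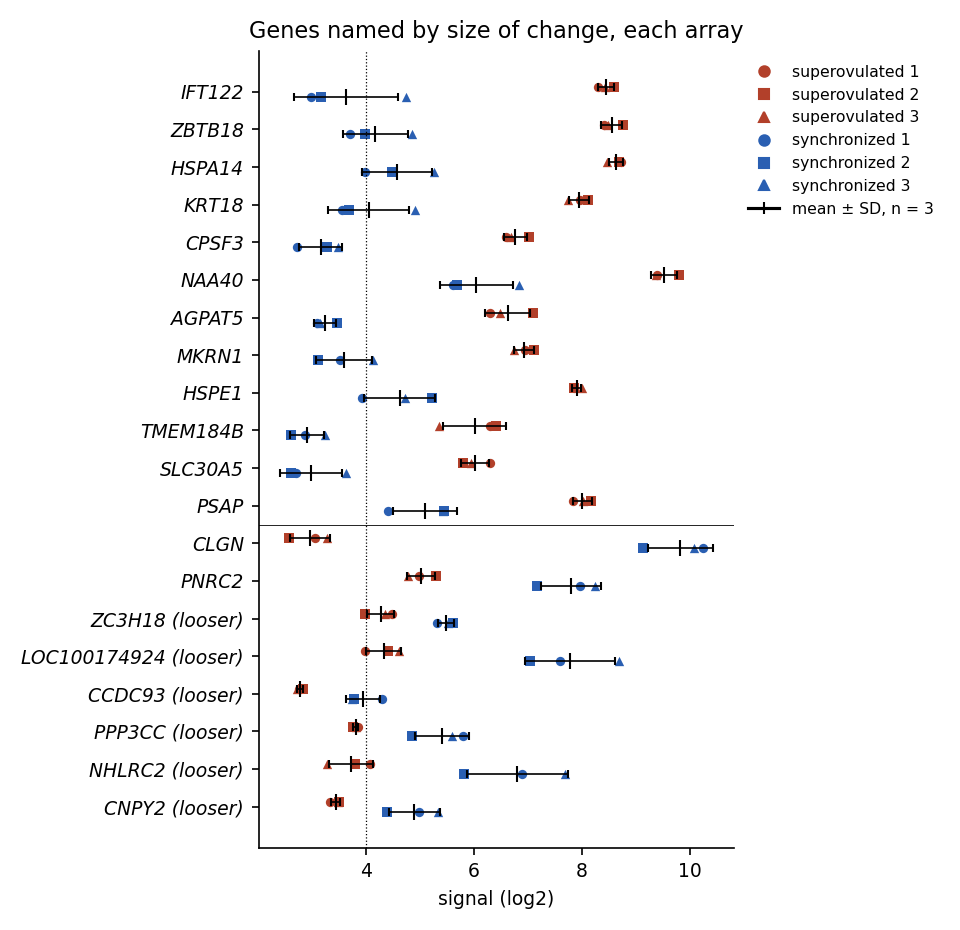
Signal (log2) of each gene named by size of change, one point per array, with the group mean and SD as a black bar; red points are the 3 superovulated arrays, blue points the 3 synchronized arrays, and the dotted line marks log2 4. No gene shown has overlapping groups, and IFT122 moved from 3.62 to 8.44 while CLGN moved from 9.82 to 2.96; genes marked looser passed only the second threshold.

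In all, 172 probe sets passed an adjusted p of 0.05 in limma, 167 higher and 5 lower in the superovulated group, and all 172 had no overlap between the arrays of the groups. The groups did not overlap in 13.3% of all probe sets tested, against 10% by chance. Calls with a symbol covered 126 genes. The looser threshold gave 456 probe sets, 431 higher and 25 lower. Of the 167 rises, 121 had a synchronized mean under log2 4. The 1406 probe sets with a mean above log2 4 were shifted as a body, 1009 higher and 397 lower with a median difference of 0.59, whereas the median over all probe sets was -0.02. The rises were 97.1% of the calls and 94.5% of the looser calls. In a test of the 1406 bright probe sets alone these shares were 93.7% and 94.2%, and once each array was also centred on them 208 of 258 calls (80.6%) and 310 of 507 looser calls (61.1%) were rises. The count changed with the arrays used: it was 78, 26 and 54 without superovulated arrays 1, 2 and 3, 60, 137 and 46 without synchronized arrays 1, 2 and 3, and 1 without both superovulated array 3 and synchronized array 2. Without synchronized array 2 the 137 calls were 96 rises (70.1%) and 41 falls. It was 28 after a second quantile normalization.

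**Figure D2:**
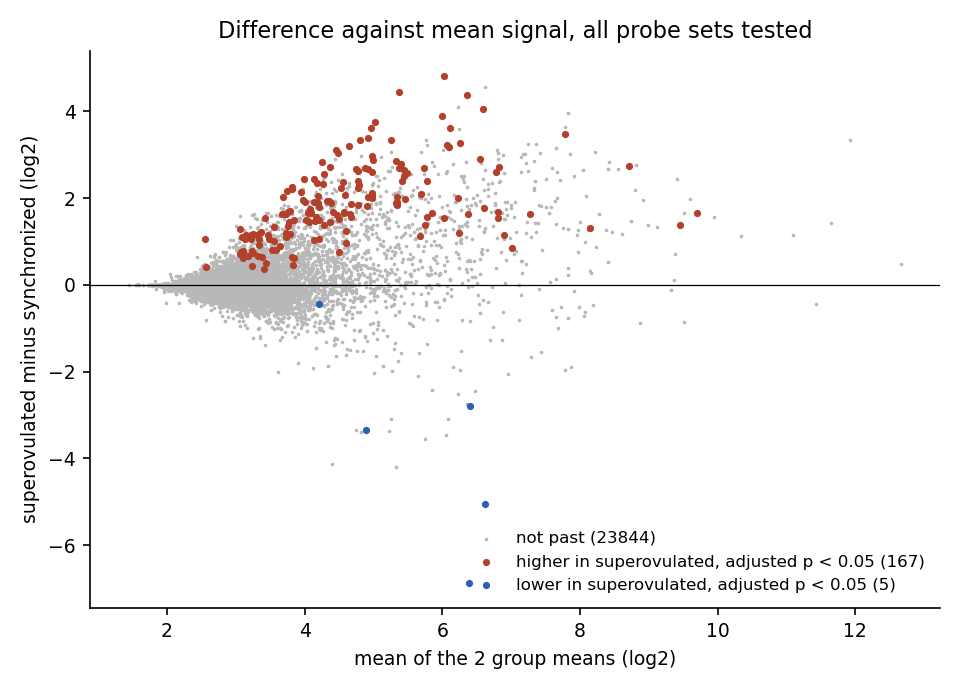
Difference between the groups (superovulated minus synchronized, log2) against the mean of the group means (log2), one point per probe set tested. Red points are the 167 probe sets higher and blue points the 5 lower in the superovulated group at an adjusted p below 0.05; grey points did not pass.

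Cytosolic ribosomal proteins and the respiratory chain were higher as groups by camera, with adjusted p = 1.59e-33 and adjusted p = 2.72e-29. Neither passed with an estimated correlation, at adjusted p = 0.119 for the ribosomal proteins and adjusted p = 0.0691 for the respiratory chain. Of 67 measured ribosomal protein genes 8 rose and 0 fell in the test over all probe sets, and 50 rose when p was adjusted over the list alone, with a list median of 1.72. RPL31 rose from 8.77 ± 0.15 to 10.15 ± 0.11, RPS21 by 2.07 and RPL22 by 2.08. The list mean was 6.28, 6.59 and 6.50 on superovulated arrays 1 to 3 and 4.37, 5.42 and 5.03 on synchronized arrays 1 to 3. In the respiratory chain and ATP synthase list 9 of 79 members rose, 43 adjusted over the list alone, 0 fell, and the median was 0.79. COX5A, a subunit of cytochrome c oxidase, rose by 2.84, the ubiquinol-cytochrome c reductase gene UQCR11 by 2.51 and the complex I gene NDUFV1 by 1.15. NDUFV1 lay near background, with means of 2.57 in the synchronized and 3.73 in the superovulated group. Among bright probe sets alone both still stood above the other genes by camera (adjusted p = 1.14e-05 and 2.79e-05). After centring on bright probe sets camera gave adjusted p = 2.06e-08 and 1.31e-05, with medians of 1.20 and 1.10. Centring takes the same value from every bright probe set of an array. It therefore leaves the gap in log2 difference between a list and the other bright genes unchanged, and is no separate support. Against synchronized array 2 alone, which had as many bright probe sets as the superovulated arrays, the medians of both lists were 1 and 0.62.

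The heat shock and unfolded protein response list was higher by camera (adjusted p = 0.000385), but not with an estimated correlation (adjusted p = 0.119). Of its 36 genes 4 rose (6 adjusted over the list alone) and 0 fell: HSPA14, HSPE1, HSPA4 by 2.40 and the mitochondrial HSPA9 by 1.5. Over all 36 the median difference was 0.10, with 21 differences above 0. The 13 members with a mean above log2 4 had a median difference of 1.5, and all 13 differences were above 0. Tested by camera among bright probe sets these 13 gave adjusted p = 0.0630, and 0.0195 after centring on bright probe sets. The centring leaves their gap in log2 difference to other bright genes unchanged, so the lower value is no separate support. Other probe sets of HSPA4 and HSPA9 did not pass and lay at -0.30 and -0.35.

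A further 8 lists were higher by camera, and with an estimated correlation none passed, at adjusted p = 0.134 for chromatin regulators, adjusted p = 0.174 for inner cell mass and adjusted p = 0.119 for the others. They were the proteasome (35 members, 1 up, median 0.32, adjusted p = 2.36e-09), splicing (61, 4 up, median 0.16, 3.48e-07), translation factors (41, 1 up, median 0.36, 3.55e-07), the tricarboxylic acid cycle (21, 1 up, median 0.22, 0.00299), mitochondrial ribosomal proteins (67, 1 up, median 0.02, 0.0220), chromatin regulators (34, 3 up, median 0.01, 0.0382), cell cycle and DNA replication (58, 1 up, median 0.01, 0.0382) and inner cell mass markers (7, 0 up, median 0.19, 0.0394). None of them had a member that fell over all probe sets, and adjusted over the list alone the rises numbered 3, 11, 8, 3, 2, 4, 1 and 3 in that order, with 1 fall among the translation factors. None of the 7 that kept at least 5 members passed among bright probe sets alone. The direction of the mitochondrial ribosomal, chromatin and cell cycle lists relative to other genes turned after centring on bright probe sets, and that of the cell cycle list turned among bright probe sets alone.

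Single genes in these lists passed the test over all probe sets. CDK1, the kinase that drives entry into mitosis, rose from 2.67 ± 0.11 to 4.70 ± 0.05 (adjusted p = 0.00469). MDH2, the mitochondrial malate dehydrogenase, rose by 2.00, PSMB1 of the proteasome core by 1.15, the initiation factor gene EIF5 by 1.44 and MRPS31 by 2.38. The PSMB1 means, 2.73 in the synchronized and 3.88 in the superovulated group, lay near background. Among splicing genes SRSF3 rose by 1.57, SRSF1 by 0.75, HNRNPK by 1.30 and HNRNPAB by 1.68. Among chromatin regulators the de novo DNA methyltransferase gene DNMT3A rose by 1.67, the deacetylase gene SIRT1 by 1.56 and the arginine methyltransferase gene PRMT5 by 0.40, the last between 2.37 and 2.77 near background. Further probe sets of MDH2, EIF5, SRSF1, DNMT3A and SIRT1 differed by at most 0.05 in the direction of the rise and did not pass.

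**Figure D3:**
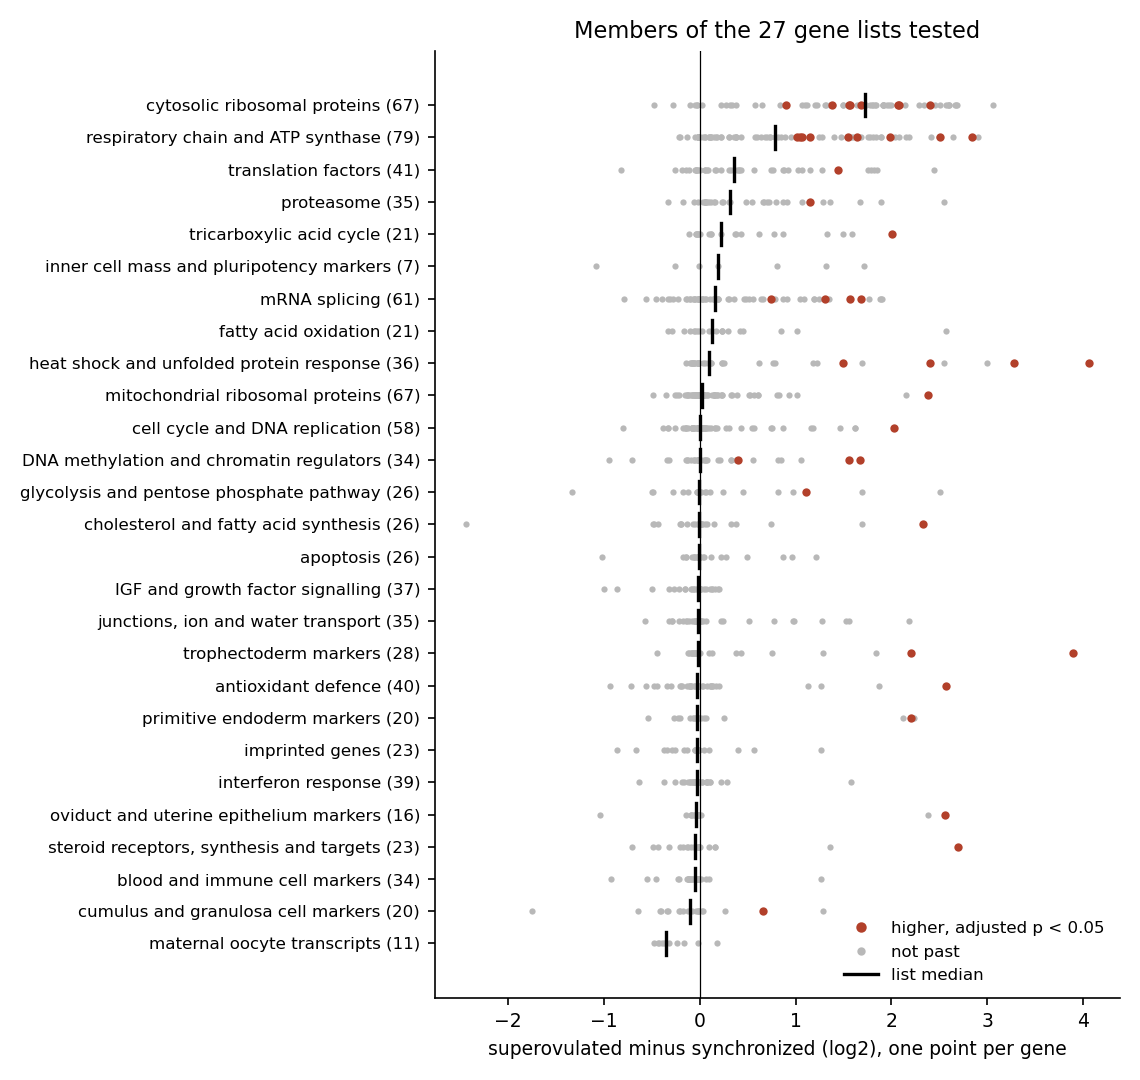
Difference between the groups (superovulated minus synchronized, log2) of each member of the 27 gene lists tested, one point per gene, with the list median as a black bar and the number of members in brackets. Red points passed an adjusted p of 0.05 over all probe sets; the median was 1.72 for cytosolic ribosomal proteins and 0.79 for the respiratory chain and lay near 0 for most lists.

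The trophectoderm, primitive endoderm and junction lists did not pass camera, though single members rose. KRT18 and DAB2, an endocytic adaptor of extraembryonic epithelia held by both the trophectoderm and the primitive endoderm lists, were the members that rose (DAB2 by 2.21, adjusted p = 0.0387, with -0.13 on a second probe set). The trophectoderm list (28 members, 2 up, 4 adjusted over the list alone) gave adjusted p = 0.307, the primitive endoderm list (20, 1 up, 3 over the list alone) 0.975, and the junction and transport list (35, 0 up, 3 over the list alone) 0.330, with 0 falls in each. Differences that did not pass were 2.12 for GATA6 and 2.23 for FN1 of the primitive endoderm, and 2.18 for EZR, the membrane-cytoskeleton linker of the apical surface. The pluripotency gene POU5F1 differed by 0.81 (adjusted p = 0.0886), with means of 3.40 and 2.59 near background. SOX2, KRT8 and OVGP1 read between 2.20 and 2.42 in both groups, so their probe sets gave no usable signal. NANOG, CDX2, GATA3 and IFNT had 0 probe sets under those symbols.

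Maternal oocyte transcripts varied widely between arrays of the same group, and their difference between the groups did not pass. The list of 11 genes, 0 of which passed over all probe sets or adjusted over the list alone, had a median of -0.35 (camera adjusted p = 0.0867). Its mean was 3, 3.05 and 3.67 on superovulated arrays 1 to 3 and 2.88, 4.45 and 3.22 on synchronized arrays 1 to 3. KPNA7, an oocyte nuclear import factor, read 5.94, 5.98 and 7.78, then 4.04, 9.02 and 6.11 in the same order of arrays. The zona pellucida gene ZP2 read 3.31, 3.44 and 4.83, then 2.78, 6.14 and 3.94. KPNA7 and ZP2 were chosen after their values were seen, from the 5 list members that exceeded log2 4 on at least 1 array. The list passed, lower in the superovulated group, after a second quantile normalization (adjusted p = 0.0323), with median centring (0.0364), and without superovulated array 3 (0.0335), synchronized array 1 (0.0105) or synchronized array 3 (0.00783). Without synchronized array 2 it gave adjusted p = 0.917 and a mean difference of 0.19, so the lower value rested on that array. None of these calls allowed for the correlation between the list's genes, which was estimated at 0.753, and with all arrays the list gave adjusted p = 0.775 with an estimated correlation.

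**Figure D4:**
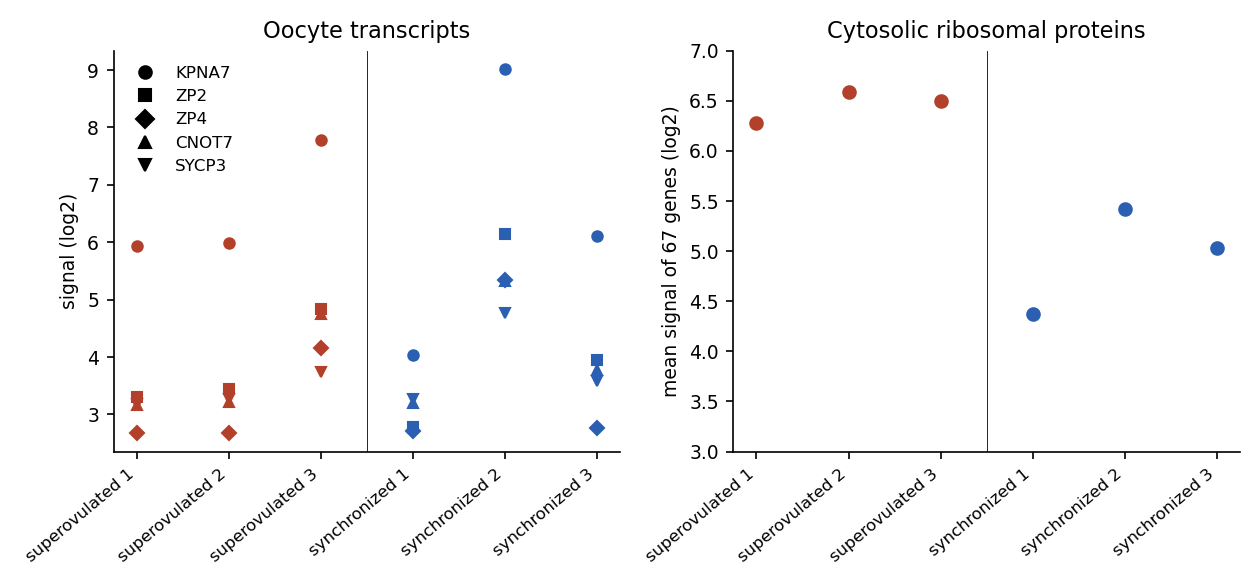
Left, signal (log2) of the 5 maternal oocyte transcripts that exceeded log2 4 on at least 1 array, one point per gene and array; right, mean signal (log2) of the 67 cytosolic ribosomal protein genes on each array. Superovulated arrays are red and synchronized arrays blue: oocyte transcripts were highest on synchronized array 2 and superovulated array 3, whereas the ribosomal protein mean was 6.28 to 6.59 on every superovulated array and 4.37 to 5.42 on every synchronized one.

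Markers of other tissues were mostly at background. The blood and immune list (34 genes, 0 up, 0 down, also adjusted over the list alone) had 0 members with a mean above log2 4 and a median of -0.05, and was lower by camera (adjusted p = 0.0279) but not with an estimated correlation (adjusted p = 0.759). In the oviduct and uterus list (16 genes, 1 up, 2 over the list alone, adjusted p = 0.870) the complement gene C3 rose by 2.56 on 1 of its 3 probe sets and EPCAM, which the embryo expresses too, differed by 2.38. In the cumulus and granulosa list (20 genes, 1 up, 2 over the list alone, adjusted p = 0.870) the collagen gene COL1A2 rose from 3 to 3.66, near background. TNFAIP6, a hyaluronan-binding protein of the cumulus matrix chosen after its values were seen, read 3.05, 2.99 and 7.38 on the superovulated arrays and 4.25, 8.47 and 5.96 on the synchronized arrays.

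The remaining lists did not pass camera. Glycolysis and the pentose phosphate pathway (26 genes, adjusted p = 0.0867) had 1 rise, the fructose transporter gene SLC2A5 at 1.11 on 1 of its 3 probe sets, and a difference of 2.51 in TKT that did not pass. The SLC2A5 means, 2.53 in the synchronized and 3.65 in the superovulated group, were near background. Antioxidant defence (40 genes, adjusted p = 0.975) had 1 rise, the peroxiredoxin gene PRDX1 at 2.57, with 1.87 in PRDX2 that did not pass. Cholesterol and fatty acid synthesis (26 genes, adjusted p = 0.497) had 1 rise, the sterol isomerase gene EBP at 2.33. Steroid signalling (23 genes, adjusted p = 0.714) had 1 rise, HSD17B11 at 2.70. No member passed in fatty acid oxidation (21 genes, adjusted p = 0.115), apoptosis (26, 0.714), interferon response (39, 0.409), imprinted genes (23, 0.556) or growth factor signalling (37, 0.596). Adjusted over the list alone these 9 lists had 4, 3, 2, 1, 1, 0, 0, 0 and 0 rises and 0 falls. The mean was above 0 and the median below it in the glycolysis, antioxidant, cholesterol, steroid, apoptosis, trophectoderm, primitive endoderm, junction, and oviduct and uterus lists. Camera's direction was that of the median and not of the mean in the antioxidant, steroid, and oviduct and uterus lists, and that of the mean in the other 6.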

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

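Of the tests in this part, only the comparison with synchronized array 2 alone was written down before its result was seen; centring on bright probe sets, the count of probe sets outside the superovulated range and the splits of the arrays were chosen afterwards.

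The control probe sets, which the group comparison does not use, carried a signal that differed between arrays. The hybridization controls were 0.813 log2 units higher on the synchronized arrays than on the superovulated ones, with 11.60, 11.20 and 12.20 on synchronized arrays 1 to 3 and 10.82, 10.88 and 10.86 on superovulated arrays 1 to 3. The poly-A controls, spiked into the RNA before labelling, read 8.51 on synchronized array 3, which was 1.35 above the next highest array. The GAPDH 3' minus 5' difference was 6.11 ± 0.07 on the superovulated arrays and 5.30 ± 0.64 on the synchronized ones (exact permutation test, p = 0.1, the smallest possible), with the 5' probe set near background on all 6 arrays.

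A uniform difference in brightness left by the normalization stays open as a cause of the surplus of rises, 167 against 5. Centring each array on the 1406 bright probe sets took the calls among them from 413 rises and 28 falls to 208 and 50. The share of rises went from 93.7% to 80.6%, and that of the looser calls from 94.2% to 61.1%. A surplus remained among the calls, so such a difference may not be the whole cause. The centring acts on the balance of the same probe sets, however, so this test cannot settle it. A weak sample signal on synchronized arrays 1 and 3 may account for part of the surplus. The hybridization controls argue against a weak hybridization step, as far as normalized values can show. They read 11.60 and 12.20 on these arrays, against 11.20 on synchronized array 2 and 10.82 to 10.88 on the superovulated arrays. Since they were spiked in and are no part of the embryos' RNA, they do not argue against a weak sample signal. Synchronized array 2, as bright as the superovulated arrays, had 388 probe sets at least 1 log2 unit below all superovulated arrays. It had 413 at least that far above them. The numbers were 728 and 126 on synchronized array 1 and 497 and 47 on synchronized array 3. Superovulated arrays 1 to 3 had 28, 4 and 9 that far below the other 2 and 13, 17 and 383 above them. The fit with synchronized array 2 alone holds 1 array in that group, so its p-values carry no spread within it. Falls outnumbered rises among its calls, but nearly all of those falls had a mean of log2 4 or less. Synchronized array 2 also held the most oocyte transcript. A weak sample signal and a real shortage of falls therefore cannot be told apart on this single array. The 10 splits of the 6 arrays into groups of 3 are too few for a share under 0.05; the real split gave 172 calls and 1596 probe sets at an unadjusted p under 0.05, the highest other gave 0 calls, and the split of superovulated array 1 with synchronized arrays 1 and 3 from the rest gave 0 calls and 1459 such probe sets, which points to a second structure of the arrays. The reproductive tract and the transfer on day 2, joined in this design, stay open as untested biological causes.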

How the results depend on the processing

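Of the settings below, centring on bright probe sets or on hybridization controls, synchronized array 2 alone, and leaving out superovulated array 3 with synchronized array 2 were chosen after seeing the data. Calls at an adjusted p of 0.05, 172 as deposited (167 higher, 5 lower in the superovulated group), numbered 28 (27 and 1) after quantile normalization, 149 (146 and 3) after median centring, 441 (413 and 28) among probe sets with a mean above log2 4, 338 (323 and 15) among probe sets with a mean above the median of all, 515 (456 and 59) with array weights, 94 (92 and 2) with an intensity trend and robust prior, 7 (4 and 3) in an ordinary equal-variance test per probe set, 258 (208 and 50) with bright probe sets, those above log2 4, centred and tested alone, 638 (624 and 14) with hybridization control centring among probe sets above log2 4, where the filter alone gave 441, 802 (141 and 661) with synchronized array 2 alone, and 1 (0 and 1) without superovulated array 3 and synchronized array 2, where limma still gave 2447 probe sets at an unadjusted p under 0.05 against 1596 with all arrays. The filters and both centrings on bright probe sets or controls test fewer probe sets, and the last setting has fewer arrays. With synchronized array 2 alone the p-values carry no spread within the synchronized group. The counts of that setting, here and below, are therefore not comparable with the others. Otherwise the cause was not tested. Without 1 array the count ran from 26 to 137, the rises from 26 to 96 and the falls from 0 to 41: it was 78, 26 and 54 without superovulated arrays 1, 2 and 3, and 60, 137 and 46 without synchronized arrays 1, 2 and 3. The 41 falls, beside 96 rises, came without synchronized array 2. Only 22 of the 28 calls after quantile normalization, and 18 of the 26 without superovulated array 2, were among the 172.

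At an adjusted p of 0.3 and 2-fold, 456 as deposited (431 and 25), the counts were 247 (232 and 15) after quantile normalization, 956 (884 and 72) with array weights, 267 (255 and 12) in the ordinary test, 357 (343 and 14) with 1 probe set per gene, 553 (521 and 32) among probe sets with a mean above log2 4, 507 (310 and 197) with these alone centred and tested, 887 (867 and 20) with these alone after hybridization control centring, and 687 (394 and 293) with synchronized array 2 alone. Leaving out 1 array gave 280 to 662, with 269 to 622 rises and 11 to 40 falls. The labels do not say whether the array numbers 1 to 3 pair the samples. Deviations of same-numbered arrays from their group means correlated at 0.54, -0.40 and -0.41. Of the 3 superovulated arrays 1 correlated best with its own number. These correlations cannot settle the pairing, since 1 component, described below, held 72.4% of the variance within groups. With the number as a replicate block limma gave 0 calls (0 higher, 0 lower), 1382 probe sets at an unadjusted p under 0.05, and 327 looser calls (311 and 16).

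The 14 named genes past 0.05 kept their direction under all 18 settings that tested them. This is no test of stability, since the naming rule kept only genes whose groups did not overlap. Leaving out arrays or adding the block cannot reverse such a gene. All 14 also passed with the filters, the array weights, and both centrings of bright probe sets, 11 with median centring, 9 with an intensity trend and robust prior, and 1 after quantile normalization. Without superovulated arrays 1, 2 and 3 in turn 2, 1 and 2 passed, and without synchronized arrays 1, 2 and 3 in turn 4, 6 and 7. None passed, 0 in each case, with the replicate block, in the ordinary test, or without superovulated array 3 and synchronized array 2.

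Lists called by camera were 11 higher and 1 lower as deposited. They numbered 7 higher after quantile normalization, and 2 higher and 0 lower among probe sets above log2 4. The numbers were 3 and 0 with bright probe sets centred, and 2 and 0 with hybridization control centring of the same probe sets. With an estimated correlation they were 0 and 0. Median centring gave 2 lower, probe sets above the median of all 0 lower, and fry 14 higher and 0 lower. With median centring cell cycle (camera adjusted p = 0.0779), inner cell mass (0.078) and chromatin regulators (0.083) no longer passed as higher. Among probe sets above the median of all, mitochondrial ribosomal proteins (camera adjusted p = 0.105), cell cycle (0.127) and chromatin regulators (0.163) no longer passed. Leaving out 1 array gave 8 to 11 higher and 0 to 2 lower. The direction relative to other genes was reversed for mitochondrial ribosomal proteins (mean 0.14) and chromatin regulators (mean -0.0871) with bright probe sets centred, and for cell cycle among probe sets above log2 4 (0.38), with bright probe sets centred (-0.24) and with hybridization control centring (1.19); only brighter members entered these tests. Most probe sets lay near background, which limits what these arrays can show for dim genes.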

Other observations

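All tests on the variation within groups were chosen after it was seen, while the percentile of the lineage genes was written down before its result and the checks on it were added afterwards.

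A large set of genes varied together among arrays of the same group. The first component of the deviations from the group means held 72.4% of the variance within groups, with loadings of -0.23, -0.14 and 0.36 on superovulated arrays 1 to 3 and -0.53, 0.70 and -0.17 on synchronized arrays 1 to 3. Its leading genes, named here after their values were seen, included HMGCS1, the cytosolic synthase of cholesterol synthesis, at 3.01, 4.40 and 8.34 on the superovulated arrays and 5.11, 10.31 and 7.65 on the synchronized ones. HIF1A, the oxygen-regulated transcription factor, read 3.37, 3.73 and 8.54, then 5.14, 9.47 and 6.68, and the homeobox gene MSX1 read 3.80, 5.50 and 8.48, then 5.80, 10.38 and 7.78. The Polycomb gene EED, the cyclin kinase partner CKS1B, the ubiquitin hydrolase UCHL1 and the planar polarity gene PRICKLE1 had the same order of arrays at the top, synchronized 2 and then superovulated 3. These genes were also lower on average in the superovulated group, by differences such as -2.44 for HMGCS1, -2.75 for PRICKLE1 and -2.06 for MSX1. With this spread none passed (adjusted p by limma 0.636 for each of these 3), which does not show that the groups were alike.

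A candidate explanation for this variation is that maternal oocyte transcripts were present in different amounts. The 5 oocyte genes above log2 4 on at least 1 array correlated within groups at 0.964, at the 100th percentile of 10000 random lists matched on mean expression. That filter depends on the variation itself: 4 members exceeded log2 4 on superovulated array 3 and 5 on synchronized array 2, against 1 on each other array. Over all 11 members the correlation was 0.753, also at the 100th percentile. Of the 23 lists with at least 5 members above log2 4 on an array, 3 lay above the 95th percentile. The others were translation factors (0.474) and the proteasome (0.458). Over all members at any level the trophectoderm list (0.354) was at the 100th percentile too, so the measure is not particular to oocyte genes. A brighter superovulated array 3 stays open as well. Its ribosomal protein mean was only 0.069 above that of arrays 1 and 2 while the oocyte mean was 0.646 above, which argues against an even brightening. But it had 1894 probe sets above log2 4, against 1457 and 1578 on arrays 1 and 2. The median of its bright probe sets was 5.39, against 4.99 and 5.19. Cumulus or granulosa cells could not be judged, since the 8 members above log2 4 went both ways (percentile 9.28), nor could oviduct or uterine epithelium with 3 such members (percentile 55.4, and 98.4 over all 16 members, mostly at background).

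Among the blastocyst genes, 12 trophectoderm, primitive endoderm and junction members had a mean above log2 4, and 9 of them were higher in the superovulated group, with a median difference of 1.54. The general shift of bright probe sets may account for this: random bright lists matched on mean expression had a median of 0.783, and although the observed median lay at their 97.6th percentile, that bound treats genes as independent. Against the other bright genes the 12 gave p = 0.267 by camera and p = 0.452 with an estimated correlation. The percentile was 79 without synchronized array 2, and between 95.4 and 99.2 when each of the other arrays was left out in turn. A change of these genes and the general shift therefore cannot be told apart. KRT18 was the 1 member of these 12 with a call, EZR, FN1, GATA6 and LGALS3 differed by 2.18, 2.23, 2.12 and 1.84 without passing, and CSN2, GJA1 and ATP1B1 differed by -0.45, -0.57 and -0.32. The reproductive tract and the transfer on day 2 were not tested apart.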
